A study of Drosophila melanogaster with 2 samples.

How the data were processed

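Chromatin immunoprecipitation followed by sequencing was carried out on whole Drosophila melanogaster embryos aged 0 to 24 h. The embryos came from a transgenic line that makes Scr, the Hox protein Sex combs reduced, fused to eGFP. Per the labels, chromatin was sheared by sonication to 200 to 800 bp and the fusion protein was pulled down with an antibody against GFP, although the labels' antibody field names Scr itself. There were 2 biological replicates in 1 group, and no other condition, so no comparison between groups and no pairing was possible. The sex of the embryos was not collected, per the labels.

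The deposited files were lists of peaks on the dm6 assembly, per the submitters' file notes. Each replicate had its own lists, made from that replicate's alignments and a set of control alignments, and the series-level lists were made from the alignments of both replicates and the control set, per the same notes. A ranked list holding all entries and a thresholded list were used for each replicate, and the series level had a main and a conservative thresholded list with a ranked list each, which makes 4 thresholded and 4 ranked lists. The notes name 1 further input for the thresholded lists that the ranked lists do not have; what it holds is not given in the sources used here. The aligner, the peak caller, their versions and their filters are not given in the sources used here. Signal tracks and the control library itself were not used here.

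The authors' lists give each peak a score capped at 1000, and the scores in all 4 ranked lists lay within 1 unit of a scaled −log2 of the deposited irreproducible discovery rate (IDR) for 100% of entries. The lowest score in every thresholded list was 830, at which the IDR was 0.01. The −log10 IDR values that the authors deposited were capped at 5, and the −log10 q-values were not used to rank peaks. The signal of a peak is the authors' own value per peak, and its scale relative to depth or to the control is not given in the sources used here. It was used only to describe and rank peaks within a list and to correlate the replicates. The summit is the deposited offset from the peak's start. The ranked lists held 8 further columns per list that could not be tied to an input, and these were not used. Sequencing depth is unknown from the files, so no interval or detection limit that needs it is given.

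Genes and sequence came from release 6 of the genome with the Ensembl annotation BDGP6.54 of release 115, whose chromosome names and lengths fit the deposited coordinates. The annotation held 13968 protein-coding genes. All coordinates are dm6 and counted from 1. The main list was the series-level thresholded list that is not the conservative one, restricted to the arms 2L, 2R, 3L, 3R, 4, X and Y, with 1 summit per peak. A summit was assigned to a promoter when it lay within 500 bp of a protein-coding transcription start site (TSS), then in order to a 5′ UTR, a 3′ UTR, coding sequence, an intron or other genic sequence, or intergenic sequence. A gene was counted as having a peak when a summit lay in its body or within 2 kb of either end.

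The sharing of peaks between replicates was tested against 1000 rotations of replicate 2's peaks around each arm, one-sided, with an overlap of at least 1 bp. The classes of summits were tested against 1000 rotations of the summits, two-sided. Gene lists were compared with 10000 random lists of protein-coding genes matched on window length in 20 bins, two-sided. The random lists were not matched on position. List members that lie side by side were therefore counted as independent, and the p-values can be too small for such lists. The density of summits in the Hox complexes was placed among 10000 random windows of the same length, two-sided. Signal at promoters was compared with signal elsewhere by a permutation test with 100000 resamples, two-sided. DNA sites were sought on both strands within 50 bp of the summit, a window of 101 bp, and in 1 window of the same size centred 500 bp away on a randomly chosen side, and compared by the exact McNemar test, two-sided. All 2080 distinct sequences of 6 bases were tested in the same way. Sites in the 1144 strongest and the 1144 weakest peaks by signal, of 5 parts of equal size, were compared by Fisher's exact test, two-sided. Adjusted p-values are Benjamini-Hochberg values over the 6 classes, the 21 lists, the 17 sites or the 6-base sequences, and the threshold was 0.05. Shares of summits have Wilson 95% intervals, and ratios of discordant peaks have exact 95% intervals. These intervals cover counting error only. Peaks and genes are not replicates, so every p-value here describes the positions within these lists and not the spread between embryos.

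The lists of genes, the sites, the tests and the rule for the genes named were fixed before the data were examined. The rule took the genes of the 15 strongest main peaks, the 8 Hox genes, the 3 members with the strongest peak and up to 2 members without a peak from each other list, the genes of the 3 strongest peaks present in only 1 replicate's list, and the 10 sequences of 6 bases with the highest ratio of summit to flank. A peak belonged to the gene whose body held the summit, or else to the nearest TSS. The lists were the Hox genes, other genes of the Antennapedia complex, Hox cofactors, salivary gland genes, gap, pair-rule, segment polarity and dorsoventral genes, regulators of mesoderm and muscle, structural muscle genes, neural genes, head and appendage genes, gut and endoderm, trachea, haemocyte and fat body, germ line, signalling, ribosomal proteins, the proteasome, cuticle proteins of the Cpr family, and odorant and gustatory receptors. The symbols h, nos and Dl appear as hry, nanos and Delta in the annotation. Scrambled forms of the 3 Hox sites served as controls: TTATAA for TAATTA, TATKATA for TTAATKA and TATGTDTA for TGATTDAT.

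The alternatives tried before looking at their outcome were the conservative list, the peaks above the median signal, each replicate's own list, merged overlapping peaks, other overlap rules, other windows around genes and summits, other flanks, shuffled sequence and the removal of peaks within 100 kb of Scr. Windows at promoters without a peak, summits away from promoters, promoter summits by strength, the retention of ranked entries at the listed score, summits at a gene's own TSS, the other pairings of replicate peaks and the rotation of main peaks against the ranked lists were added after seeing the data. Replicate overlap, summit classes, gene lists, sites, sequences of fixed length, peak strength, complex density and promoter signal were each tested on simulated data. The correlation of replicate signals, the backgrounds chosen after seeing the data and the closing observations were not. Of 20 draws of genes at random over the 21 lists, 1 list was called in all. With random summits, windows and positions 0 classes, 0 sites and 0 complexes were called. Genes drawn at random do not reproduce lists whose members lie side by side. Random windows lack the differences between real summits and flanks, so these 0 sites do not vouch for the comparison of sites. The scrambled sites TATKATA and TATGTDTA passed on the real data. In 1 of 20 draws of random signal any site was called by peak strength. A Hox site written into 200 of 5720 simulated windows was recovered with an adjusted p of 1.86e-08. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Peaks on the mitochondrial genome and on unplaced contigs were left out of all comparisons.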

Results

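The study mapped where Scr-eGFP is recovered on the genome of whole embryos aged 0 to 24 h. Scr is the Hox protein that specifies the labial and first thoracic segments and the salivary glands. Replicate 1's thresholded list held 4483 peaks, of which 4462 lay on the chromosome arms, and replicate 2's held 4398, of which 4376 did. The main list, made from both replicates, held 5742 peaks, of which 5720 lay on the arms, 21 on the mitochondrial genome and 1 on another contig. Peaks of the main list had a median width of 544 bp, which was also the commonest width. Their median signal was 134, with an interquartile range of 84.3 to 343. Density on the arms ran from 39.0 summits per Mb on 3L to 49.7 on 2R, and the Y had 0. Of the 5720 summits, 901 (15.8%) belonged to entries that overlapped a stronger entry of the same list.

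The 15 strongest peaks were named by their genes. The strongest had its summit at 2R 21501988 (peak 21501613 to 21502317), 109 bp from a TSS of MESK2 (FBgn0043070), with a signal of 3461 in the main list, 1974 in replicate 1 and 1464 in replicate 2. The second lay 73 bp from the TSS of RhoGAP93B (FBgn0038853), a GTPase-activating protein gene, at 3R 21097900 with a signal of 3340. Rpn6, a subunit of the proteasome lid, followed with 2918 at 2R 14752374, and RpL32, a protein of the large ribosomal subunit, with 2881 at 3R 30046250. CG11857 had 2649, mtSSB, the single-stranded DNA-binding protein of mitochondria, 2574, and Mic26-27, a subunit of the mitochondrial cristae-organising complex, 2509. The next 8 genes, with signals from 2217 down to 2108, were Pp2A-29B, a scaffold subunit of protein phosphatase 2A, Sry-alpha, the proteasome gene Prosalpha7, Gp150, the translation initiation factor gene eIF3c, Capr, Creld and CG8613. All 15 summits were at promoters and all 15 peaks were in both replicates' lists. At 6 of the 15, more than 1 gene had a TSS within 500 bp, so the peak cannot be assigned to 1 of them.

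The replicates were compared to see how far their lists shared peaks. Of replicate 1's 4462 peaks, 3618 (81.1%) overlapped a peak of replicate 2, and 3554 (81.2%) of replicate 2's 4376 overlapped a peak of replicate 1. Rotated lists shared 2.46% on average and at most 4.42% (one-sided p = 0.000999, n = 1000 rotations, the smallest p they can give). The strongest peaks of replicate 1 with no partner in the list of replicate 2 lay at eIF4G1, a translation initiation factor gene (signal 191), at Snap29, which encodes a membrane fusion protein (169), and at CSN1b, a subunit of the COP9 signalosome (162). Those of replicate 2 lay at Agpat1 (176), slgA, which encodes proline dehydrogenase (154), and Crtc, a coactivator of CREB (129). Every one of these 6 lay at a promoter. The other replicate's list held a different peak in or within 2 kb of Snap29 (74.9), CSN1b (365), Agpat1 (259) and Crtc (123), but not of eIF4G1 or slgA. Entries of the other replicate's ranked list overlapped the peaks at Snap29 (117) and slgA (157) and none of the others. In the main list, 3693 peaks (64.6%) overlapped a peak of both thresholded replicate lists, 596 one of replicate 1 only, 640 one of replicate 2 only and 791 neither. An entry of both ranked lists, which are far longer (67592 and 71892 entries), overlapped 5688 main peaks (99.4%), against 22.8% of rotated main peaks, a comparison chosen after seeing the data. The main list was made from the same alignments, so overlap with these lists is largely given by construction. It is no independent measure of how well the replicates match.

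Across the 3618 shared peaks, Pearson's r of the log2 signals was 0.70 (bootstrap 95% interval 0.67 to 0.73) and Spearman's rho 0.79. The median log2 difference of replicate 1 over replicate 2 was 0.07 with an SD of 1.10. The correlation is across peaks, which are not independent, so no p is given. Peaks above the median signal of each list gave r = 0.91 and so did pairs with summits within 100 bp of each other. Each replicate 1 peak was paired with the overlapping replicate 2 peak of nearest summit, so that 724 of the pairs shared a replicate 2 peak with another pair. The signal was over 4-fold lower in replicate 1 in 246 pairs and over 4-fold higher in 25. With pairs made from replicate 2's peaks these counts were 19 and 239, and r was 0.68. In the 3254 pairs in which each peak was the other's match they were 18 and 24, with r = 0.91 and an SD of 0.54. Both of these pairings were chosen after seeing the data.

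**Figure D1:**
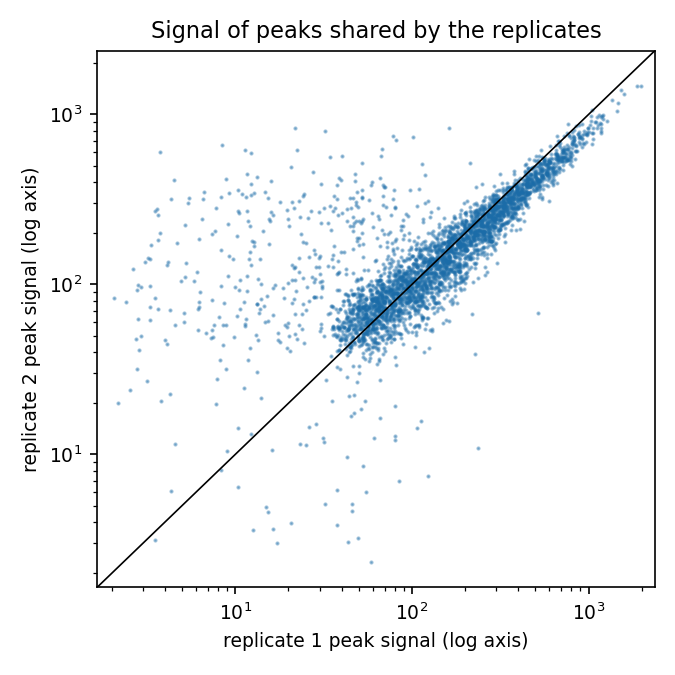
Signal of the 3618 peaks shared by the replicates, with replicate 1 on the x axis and replicate 2 on the y axis, both logarithmic and in the authors' signal units; each point is 1 pair and the line marks equal signal. Most points follow the line (median log2 difference 0.07), and the scatter of pairs with a low signal in replicate 1 comes from pairing in 1 direction, since it turns to replicate 2 when pairs are made from that side.

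Summits were then placed on the annotation, to see which parts of genes were recovered. Promoters held 4582 of 5720 summits (80.1%, Wilson 95% interval 79.1 to 81.1), against 11.5% ± 0.617 (SD of 1000 rotations) for rotated summits, a ratio of 6.96. Introns held 11.3% against 41.4% rotated, intergenic sequence 6.12% against 27.8%, 3′ UTRs 1.08% against 5.18% and coding sequence 0.857% against 13.3%. For each of these 5 classes the adjusted p was 0.0024, from the smallest raw p that the rotations can give. The 5′ UTR outside the promoter window held 28 summits, 0.490% against 0.798% (adjusted p = 0.016, n = 5720 summits), a difference that did not pass once overlapping peaks were merged (adjusted p = 0.084). The median distance of a summit to the nearest TSS was 92 bp, 52.7% lay within 100 bp, and 334 (5.84%) lay more than 5 kb away.

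Promoter peaks were also stronger than the rest. Their median signal was 156 over 4582 peaks, against 94.97 over 1138 others, a difference in median log2 signal of 0.71 (two-sided permutation p = 1e-05, the smallest that 100000 resamples can give).

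**Figure D2:**
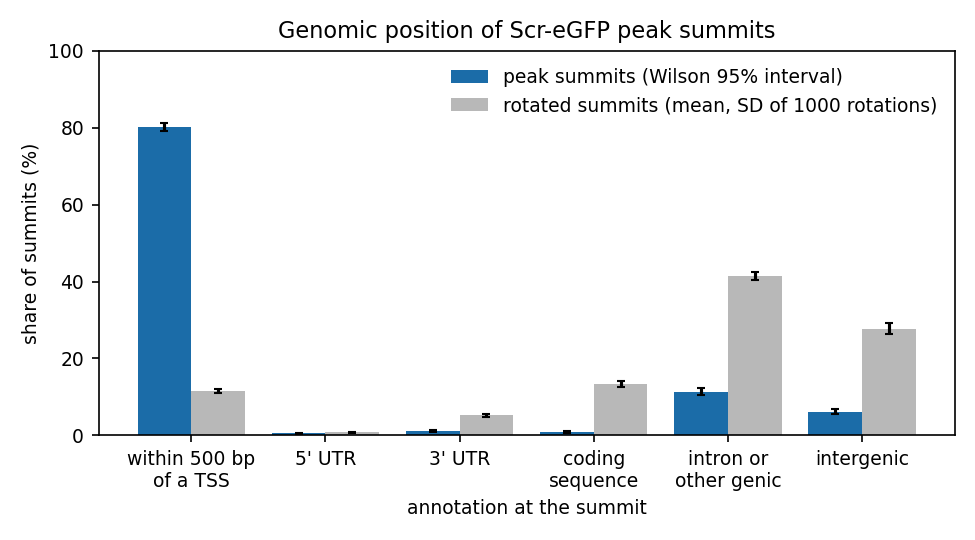
Share of summits in percent (y axis, from 0) by annotation class (x axis) for the 5720 summits of the main list (blue, Wilson 95% interval) and for rotated summits (grey, mean and SD of 1000 rotations). The blue bar reaches 80.1% at promoters and lies below the grey bar in the 5 other classes.

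The gene lists asked whether known Scr biology or general functions were represented among the 7013 of 13968 protein-coding genes (50.2%) with a summit in the gene or within 2 kb. Ribosomal protein genes had a summit at 76 of 92, against 39.8 for random genes of the same window length (adjusted p = 0.0014, n = 92 genes), led by RpL32 (signal 2881), with RpL10 and RpL10Aa among those without one. Proteasome genes had one at 33 of 48, against 22.0 (adjusted p = 0.0136, n = 48 genes), among them Rpn6 (2918), Prosalpha7 (2172) and the core subunit gene Prosbeta2 (1843), with Prosalpha3T and Prosalpha4T1 among those without one. Drawn by symbol, this list also held genes with a T or R suffix, of which only Prosalpha1R, Prosbeta2R2 and Rpt3R had a summit. Of its genes without such a suffix, only Prosbeta4 and Rpn7 lacked one. Cuticle proteins of the Cpr family had a summit at 10 of 70, against 29.3, and odorant and gustatory receptors at 16 of 119, against 58.5 (adjusted p = 0.0014 for both, n = 70 and n = 119 genes, from the smallest raw p that 10000 random lists can give, as for the ribosomal proteins). Structural muscle genes had one at 2 of 14, against 8.14 (adjusted p = 0.0151, n = 14 genes). These were Tm1 (tropomyosin, 332, at a start shared with MRG15) and TpnC73F (troponin C, 159, at the start of Pop5). None lay at the actin genes Act57B and Act87E. The 16 other lists did not pass, with adjusted p-values from 0.0665 for the signalling genes to 1.

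A summit in a gene's window was often at a neighbour's promoter. The strongest peak in the window of RpS13 was that of Pp2A-29B, and that of RpS2 lay at the TSS of Bka. For the cuticle genes Cpr73D, Cpr31A and Cpr60D the peaks lay at the starts of Ogdh, Pen and ND-19 with CG30161, for Or9a at Neb-cGP and for Gr59e and Gr59f at AIMP3. With summits counted only within 500 bp of a gene's own TSS, a setting chosen after seeing the data, the 5 lists still passed, with 60 of 92 ribosomal protein genes, 28 of 48 proteasome genes, 0 of 70 Cpr genes, 3 of 119 receptor genes and 1 of 14 structural muscle genes (adjusted p = 0.0403 for the last, n = 14). The proteasome and structural muscle calls ended in replicate 2's list alone (adjusted p = 0.0521 for each, n = 48 and n = 14 genes) and with a window of 10 kb (adjusted p = 0.899 and 0.0787, n = 48 and n = 14 genes), where the excess of proteasome genes over the matched mean fell from 11.0 to 3.13. The structural muscle call also ended among peaks above the median signal (adjusted p = 0.197, n = 14 genes). With summits in the gene body only, 4 of the 5 calls ended and the receptor genes alone stayed past the threshold.

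**Figure D3:**
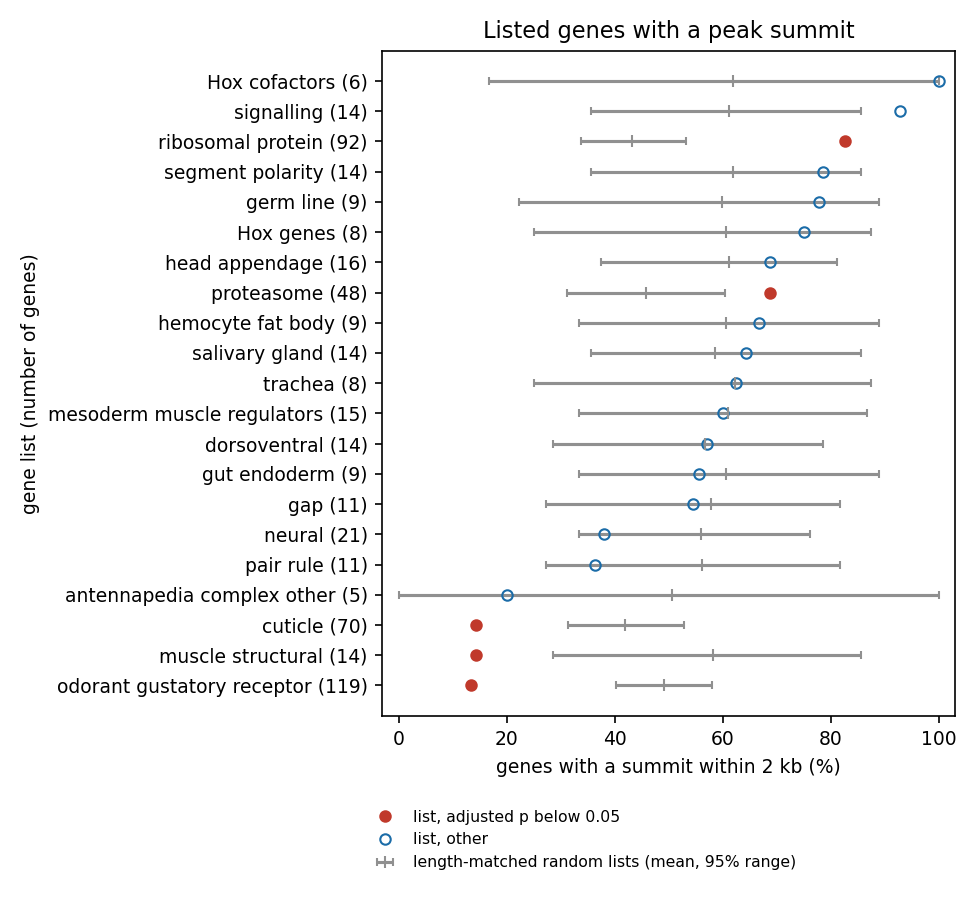
Percent of genes with a summit within 2 kb (x axis) for the 21 lists (y axis, number of genes in brackets), as filled red points where the adjusted p was below 0.05 and open blue points otherwise; grey marks give the mean and 95% range of length-matched random lists. Ribosomal protein and proteasome genes lie to the right of their random range, and cuticle, receptor and structural muscle genes to the left.

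Among the Hox genes, the homeotic selectors to which Scr belongs, 6 of 8 had a summit, against 4.85 for matched genes, which did not pass the test. Scr itself (FBgn0003339, 3R 6823120 to 6849981) had 2, the stronger of which, at 6848694 (peak 6848422 to 6848965), lay at its own promoter with a signal of 142. Replicate 1's list had 1 summit in the window of Scr, with a signal of 67.1, and replicate 2's had 0, although entries of the ranked lists there reached 117 in replicate 1 and 173 in replicate 2. Within 2 kb of Scr the main ranked list held 1 more entry at the listed score (6822886 to 6823113, signal 301), which the main list lacks. The labial gene lab had 3 summits with a strongest signal of 176, in an intron, pb had 1 of 126, abd-A 3 with 161 at its promoter and Abd-B 1 with 80.4 at its promoter. Ubx had 2, of which the stronger (343) lay at the start of the neighbouring gene modSP. Dfd had 0. Antp had 0 in the main list and 1 in each replicate's own list, with signals of 43.9 and 48.6. These signals were far below those of the strongest peaks, and that of Scr ranked 2736 among 5720.

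Of the 5 other genes of the Antennapedia complex only bcd, the anterior determinant, had a summit (signal 246, at its promoter), and Ama and ftz were among the 4 without one. All 6 genes of the Hox cofactor list had a summit, against 3.71 for matched genes, which did not pass either. They included exd, the partner that sharpens Hox site choice, with 358 at X 15992372, a start it shares with eIF5 and CG46312, tio with 199 in a 3′ UTR, and hth, which carries Exd into the nucleus, with 160 at its promoter. Salivary gland genes had a summit at 9 of 14, against 8.21. The strongest were at ps (269), at the start of GstZ1, at trh (235), in an intron, and at CrebA (229), at the start of AGO2, whereas fkh and hkb, regulators of salivary gland formation, had none in any of the main and replicate lists.

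The patterning lists did not pass either. Gap genes had a summit at 6 of 11, with oc (143) and cad (112) at their own promoters and none at gt or hb. Pair-rule genes had one at 4 of 11, among them hry (127) and odd (121) and, at the start of Atg3 and Nufip, ftz-f1 (500), and none at eve or ftz. Segment polarity genes had one at 11 of 14, with pan (674) and smo (631) at their promoters, that of smo shared with CG17078. The strongest summit of arm (513) lay at the promoters of mRpL16 and trr. None lay at fz or gsb in the main list, though fz had 1 in each replicate's own list (58.1 and 52.5). Dorsoventral genes had one at 8 of 14, with tld (561) at the start of asp, dpp (154) and rho (126), and none at Doc2 or ind. Signalling genes had one at 13 of 14, against 8.56. They included tkv, a receptor for Dpp, at 604, hh at 435, at the start of CG31457, and bnl, an FGF ligand, at 329. None lay at N in the main list, though it had 1 in replicate 2's own list (57.9). The signalling list passed when the conservative peak list was used (adjusted p = 0.0042, n = 14 genes).

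The lists for tissues gave no call beyond structural muscle. Regulators of mesoderm and muscle had a summit at 9 of 15, with Mef2 at 531 and 8 summits, tin at 685, at the start of mod(mdg4), and H15 at 209. None lay at ap or bap in the main list, though ap had 1 in replicate 1's own list (98.8). Neural genes had one at 8 of 21, against 11.7, with ey at 948, elav at 145 and toy at 137, and none at the proneural genes ac and ase. Head and appendage genes had one at 11 of 16, with kn at 621, at the start of BEAF-32, oc at 143 and Lim1 at 117, and none at ap or B-H1. Gut and endoderm genes had one at 5 of 9, with lab, srp (149) and cad, and none at GATAe or fkh. Tracheal genes had one at 5 of 8, with bnl, trh and vvl (145), and none at knrl or salm, though knrl had 1 in replicate 2's own list (71.3). Haemocyte and fat body genes had one at 6 of 9, with svp at 294, Pxn at 278, at the starts of CG42245 and MEP-1, and ush at 213, and none at gcm or lz. Germ-line genes had one at 7 of 9, with bgcn at 1789, at the start of Pym, piwi at 1525, at that of TTLL4A, and nanos at 1498, at a start shared with CG11779, and none at aub or bam.

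Taken as a whole, the Hox complexes were no denser in summits than other regions of their size. The Antennapedia complex (3R 6661427 to 6999228, from lab to Antp) held 12 summits, 3.55 per 100 kb, against a median of 4.14 in random windows with a 95% range of 0 to 10.4 (two-sided p = 0.911, n = 10000 windows). The bithorax complex (3R 16656623 to 16972236, from Ubx to Abd-B) held 7, 2.22 per 100 kb, against 4.12 with a range of 0 to 10.5 (p = 0.579, n = 10000 windows). In replicate 2's list alone the Antennapedia complex had 1.78 per 100 kb. Of its 12 summits 9 lay within 100 kb of Scr, and the remaining 110940 bp held 3, or 2.70 per 100 kb. The summits at 3R 6810790, 6812824, 6815475, 6816385 and 6819136 lay close together between Dfd and Scr, outside the 2 kb window of either gene. The test averages over the whole complex, so it does not address such a cluster. The random windows were drawn over all arms, among them the Y with its 0 summits. Their range includes 0, so a depletion could not have been found.

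**Figure D4:**
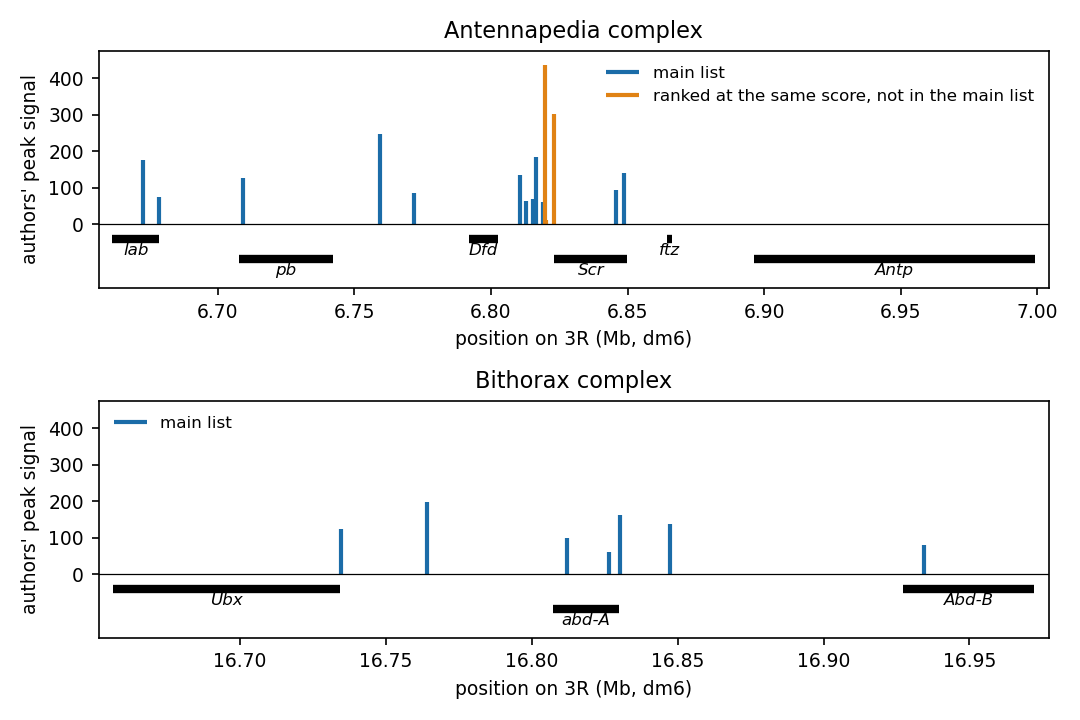
Signal of the peaks (y axis, the authors' units) along the Antennapedia complex (top) and the bithorax complex (bottom), with the position on 3R in Mb on the x axis and genes as black bars below 0; blue lines are summits of the main list and orange lines ranked entries at the same score that the main list lacks. None of the 12 blue lines of the Antennapedia complex lies within Antp, and the 3 orange lines, 1 of them of low signal, stand just beyond the 3′ end of Scr.

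DNA sites were compared between summits and flanks, to see whether Hox sites or those of other proteins marked the peaks. TATCGATA, the site of DREF, was in 12.8% of summit windows and 0.385% of flank windows (ratio 32.6, adjusted exact p = 1.76e-192), and GGTCACAC, within the site of M1BP, in 3.78% against 0.437% (ratio 8.49, adjusted exact p = 3.43e-38). Smaller differences were found for GAGAGAG, the site of GAGA factor (3.25% against 1.68%, adjusted exact p = 3.70e-07), TGACAG, the site of the Hox cofactor Hth (4.11% against 2.34%, adjusted exact p = 4.62e-07), AGRKGGCG, the site of CTCF (1.82% against 0.979%, adjusted exact p = 0.000565), and the forkhead site TRTTTAC (6.10% against 4.63%, adjusted exact p = 0.00135). The E-box CAYATG was less common at summits (5.70% against 7.41%, adjusted exact p = 0.000683). The CTCF site no longer passed in replicate 1's list (log2 0.51, adjusted exact p = 0.109), in replicate 2's (0.64, adjusted exact p = 0.0597) or among peaks above the median signal (0.46, adjusted exact p = 0.277), nor did GAGAGAG in replicate 1's list (0.33, adjusted exact p = 0.179). The Hox sites did not pass. TAATTA, the homeodomain core, was in 6.05% against 5.40% (adjusted exact p = 0.191), the monomer site TTAATKA in 5.12% against 5.16% (adjusted exact p = 1) and the composite Exd-Hox site TGATTDAT in 1.504% against 1.77% (adjusted exact p = 0.365).

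Of the 3 scrambled Hox sites, tested in the same way, TTATAA did not pass and the others did. TATKATA was higher at summits (4.13% against 3.30%, adjusted exact p = 0.0418), TATGTDTA lower (2.38% against 3.46%, adjusted exact p = 0.00144), though neither passed in either replicate's own list, and GC content was 41.7% at summits and 43.7% in flanks. In replicate 1's list alone TTAATKA and TAATTA were higher at summits (log2 0.41 and 0.51, adjusted exact p = 0.00513 and 0.000233), as was TTATAA, the scrambled form of TAATTA (0.41, adjusted exact p = 0.00446), whereas TATKATA, that of TTAATKA, was not (0.19, adjusted exact p = 0.245). Against promoters without a peak, a background chosen after seeing the data, 4 sites passed, with TATCGATA (log2 4.52), GGTCACAC (2.22) and TRTTTAC (0.39) higher and TGATAAG (−1.27) lower, whereas TGACAG (0.14, adjusted exact p = 0.556), GAGAGAG (0.20), AGRKGGCG (0.70) and CAYATG (−0.17) did not. CAGGTAR, ACYGGTT, TGATAAG and CACACAC did not pass in the main list. The direction of CACACAC depended on the peaks and the background, since it was lower at summits in replicate 1's list (log2 −0.76) and among peaks above the median signal (−0.89) but higher against flanks 2000 bp away (0.65), against shuffled sequence (1.53) and, chosen after seeing the data, more than 500 bp from a TSS (0.89). ACYGGTT was higher with windows of 100 bp either side (adjusted exact p = 0.0287), against shuffled sequence (adjusted exact p = 0.0215) and flanks 2000 bp away (adjusted exact p = 0.0151), among peaks above the median signal (adjusted exact p = 0.0313) and with ranked entries at the listed score kept (adjusted exact p = 0.0238, chosen after seeing the data). TGATAAG was lower in the conservative list (log2 −0.62, adjusted exact p = 0.0168) and in replicate 2's list (−0.67, adjusted exact p = 0.0325). With windows of 100 bp either side TAATTA was higher (0.26, adjusted exact p = 0.00114), as was TTATAA (0.29, adjusted exact p = 0.000800). Among those stronger peaks TAATTA was higher (7.31% against 4.72%), as were the scrambled TTATAA (6.71% against 4.23%) and TATKATA (5.38% against 3.85%), and GAGAGAG no longer was (−0.27).

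**Figure D5:**
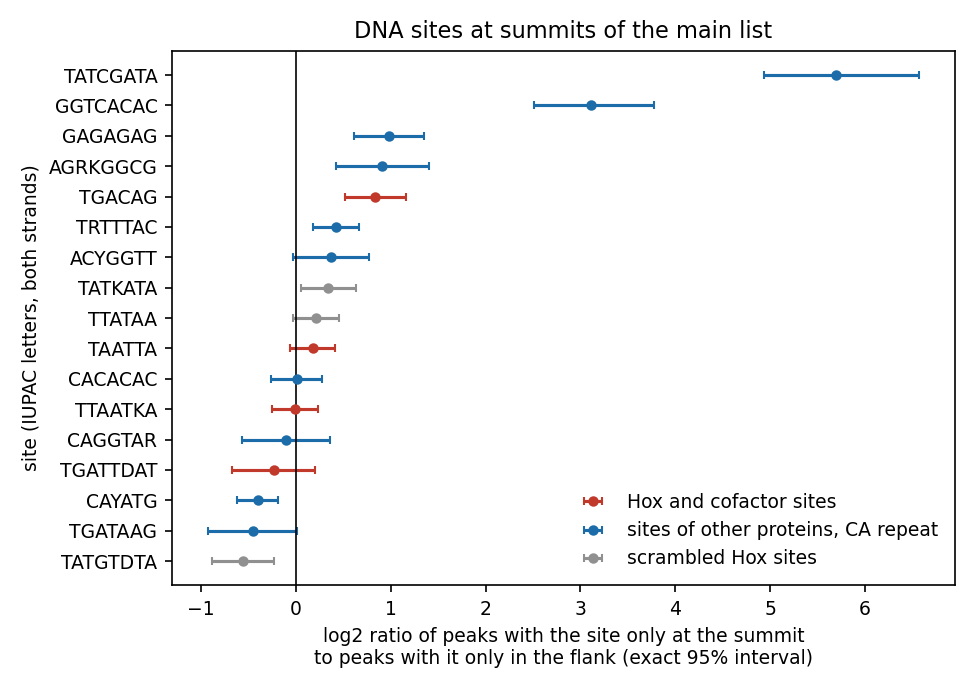
Log2 ratio of peaks with a site only at the summit to peaks with it only in the flank (x axis, exact 95% interval) for the 17 sites (y axis), over the 5720 peaks of the main list; red points are Hox and cofactor sites, blue points other sites and grey points scrambled Hox sites. TATCGATA and GGTCACAC stand apart on the right, and the 3 Hox sites lie among the scrambled ones.

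Sequences of 6 bases that were not fixed in advance were led by CGATAG. It holds CGATA, a part of TATCGATA, but does not itself lie within TATCGATA. Of 2080, 329 were more common and 522 less common at summits. The 10 with the highest ratio were CGATAG (23.2% against 2.62%, ratio 8.83), TATCGA (7.71), ATCGAT (6.89), CGATAA (4.78), CGATAC (4.49), ACTATC (4.47), CCGATA (4.41), ATATCG (4.07), CCTATC (3.41) and GCGATA (3.33), and 7 of these 10 hold CGATA on one strand. Only TATCGA and ATCGAT of the 10 lie within TATCGATA. The adjusted p of the 10 ran up to 1.77e-33.

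Sites also differed with the strength of the peak. TATCGATA was in 29.5% of the 1144 strongest peaks and 1.49% of the 1144 weakest (log2 4.27, adjusted exact p = 1.22e-88). The reverse held for GAGAGAG (0.437% against 5.16%, adjusted exact p = 2.68e-12), the repeat CACACAC (0.962% against 6.91%, adjusted exact p = 2.33e-13) and CAYATG (4.196% against 6.64%, adjusted exact p = 0.0301). TAATTA was in 7.52% of the strongest and 4.63% of the weakest (adjusted exact p = 0.0140), but the scrambled TTATAA (7.95% against 3.58%, adjusted exact p = 3.80e-05) and TATKATA (6.38% against 3.06%, adjusted exact p = 0.000792) differed in the same direction, and TAATTA did not pass in replicate 2's list (log2 0.44, adjusted exact p = 0.220). CAYATG no longer passed with overlapping peaks merged (log2 −0.59, adjusted exact p = 0.0701), among peaks above the median signal (−0.28, adjusted exact p = 0.876) or among promoter summits alone (−0.19, adjusted exact p = 0.770), the last a setting chosen after seeing the data. TAATTA (0.03) and TTATAA (0.42) did not pass among peaks above the median signal either. The 10 other sites did not pass, TTAATKA (5.86% against 4.11%, adjusted exact p = 0.132) and TGACAG (4.02% against 3.15%, adjusted exact p = 0.441) among them. TTAATKA did pass in the conservative list (adjusted exact p = 0.0417), in replicate 1's list (log2 1.04, adjusted exact p = 0.00284), with overlapping peaks merged (adjusted exact p = 0.0256) and with windows of 100 bp either side (adjusted exact p = 0.00544), though not in replicate 2's list (0.46, adjusted exact p = 0.292), and TATKATA passed in all of these. AGRKGGCG was less common in the strongest peaks with overlapping peaks merged (log2 −1.53, adjusted exact p = 0.0159) and with windows of 100 bp either side (−1.15, adjusted exact p = 0.00484). Entries that overlapped a stronger one made up 42.5% of the 1144 weakest peaks and 1.66% of the strongest. With overlapping peaks merged the log2 ratio was 4.24 for TATCGATA and −2.76 for CACACAC. Among peaks above the median signal, again cut into 5 parts, the ratio was smaller for TATCGATA (1.13), GAGAGAG (−1.96) and CACACAC (−2.21). Each of these still passed.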

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

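The tests of TTAATKA over all summits, in each peak list, and of TATCGATA in the strongest peaks were chosen only after those results were seen, and the settings restricted to summits away from promoters and to promoter summits were added after seeing the data.

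Signals outside the comparisons of the report were found in the main list's 21 peaks on the mitochondrial genome, in 163 ranked entries at or above the listed score that the main list lacks, and in 3 such entries within 100 kb of Scr. Of the 163, 94 lay on 3R and 45 on 2L, and the strongest had a signal of 2767. The 3 near Scr lay between 3R 6819763 and 6823113, next to the 3′ end of the gene, with a strongest signal of 436. The thresholded lists have 1 further input that the ranked lists lack, whose content is not given in the sources used here, and whether it removed these entries was not tested.

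The first pattern is that 80.1% of summits lay at promoters and 12.8% of summit windows held TATCGATA, whereas the Hox sites did not pass in the main list, although TAATTA was higher at summits among peaks above the median signal (7.31% against 4.72%), in replicate 1's list (log2 0.51) and with windows of 100 bp either side (0.26), as was its scrambled form TTATAA in each. TTAATKA was in 5.12% of summit windows, which does not reach most summits, but direct binding through this site at some of them or through other sites was left open, since the ratio of peaks with it only at the summit to peaks with it only in the flank was 0.993 (exact 95% interval 0.837 to 1.18) in the main list, which restates the pattern, but 1.34 (1.11 to 1.64) in replicate 1's list, with 1.15 (0.933 to 1.41) for its scrambled form TATKATA, and 1.29 (1.01 to 1.64) among peaks above the median signal, with 1.42 (1.10 to 1.84) for TATKATA. Away from promoters the ratio was 0.543 (0.356 to 0.817), with 0.633 (0.410 to 0.967) for TATKATA. Since a scrambled site was low too, the ratio cannot tell absent binding from a difference in sequence between summits and flanks. TTAATKA was in 4.04% of these summit windows, which does not reach most of them. Binding through it at some of them, other or weaker Scr sites and binding in the few cells that make Scr stay open. Recovery in proportion to transcription was left open, since ribosomal protein promoters had a median signal percentile of 63.5 among promoter summits (bootstrap 95% interval 59.6 to 76.3, 77 summits), which spans the preset bound of 75. Only promoters that held a summit entered this test, and 60 of 92 ribosomal protein genes had one at their own TSS. Promoters without a summit could not count against the explanation, and no measure of transcription was used here. A profile not set by Scr, such as regions that many pull-downs recover or a mislabelled library, may account for TATCGATA in 29.5% of the 1144 strongest peaks, but it cannot be told apart from recruitment of Scr to such promoters, because no mock or other pull-down was used here.

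The second pattern is the signal of the mitochondrial peaks, with a median of 14464 in the main list and 20 of the 21 above the strongest peak on any arm. Many copies of mitochondrial DNA per cell that the control does not balance would give peaks over much of that genome. In the replicate with less coverage the peaks covered 54.9% of its 19524 bp, narrowly above the preset bound of 50%, so this prediction held. Coverage alone cannot tell that explanation from other causes of strong peaks on that genome. The median signal of the mitochondrial peaks was 4902 in replicate 1's list and 10584 in replicate 2's. Mitochondrial DNA content was not measured, the control was not used here, and no biological explanation was tested.

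The third pattern is that TATCGATA was more common in the 1144 strongest than in the 1144 weakest peaks (29.5% against 1.49%). CACACAC was less common in the strongest (0.962% against 6.91%), so most peaks of either part lacked the site. GAGAGAG was also less common in the strongest (0.437% against 5.16%) and was not part of the checks that follow. A different mix of promoter and other summits was argued against, since within promoter summits alone the log2 ratios of the 916 strongest over the 916 weakest were 4.78 and −2.65. One replicate alone was argued against too, with 3.36 and −2.05 in the list of replicate 1 and 3.80 and −1.98 in that of replicate 2. No biological explanation was tested, and regions with repeats that any pull-down recovers weakly could still account for the CACACAC peaks.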

How the results depend on the processing

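Windows at promoters without a peak, summits more than 500 bp from a TSS, promoter summits by strength, ranked entries kept, a gene's own TSS and the other pairings of replicate peaks were settings chosen only after the results were seen; the others were fixed beforehand. Replicate overlap, the share of promoter summits, promoter signal and the 6-base counts kept their direction and side of the threshold, or stayed within 1.5 times the main count, under every alternative run for them. The density of the Antennapedia complex ran from 1.48 to 4.44 per 100 kb over the peak lists used and that of the bithorax complex from 0.951 to 2.53, and neither passed the test. Removing the peaks within 100 kb of Scr while keeping their sequence in the length lowers the density by construction, so that setting says nothing about this complex. Pearson's r of replicate signals rose from 0.70 to 0.909 for peaks above the median signal and to 0.907 for summits within 100 bp, and was 0.683 for pairs made from replicate 2's peaks and 0.907 for pairs in which each peak was the other's match. The 5 gene lists called became 1 with gene bodies only, 3 with a 10 kb window and 3 to 5 with 1 replicate left out. The 9 sites called at summits became 4 against promoters without a peak, and the 7 called by strength became 4 among peaks above the median signal. Single sites turned direction as log2 ratios of summit over background. Among peaks above the median signal GAGAGAG had −0.27 and CACACAC −0.89. With 1 replicate left out TTAATKA ran from −0.046 to 0.41 and CACACAC from −0.76 to −0.30, against −0.01 and 0.01 in the main list. Against shuffled sequence the scrambled TATKATA had −0.60 and TATGTDTA 0.46, and against promoters without a peak TATGTDTA had 0.12. More than 500 bp from a TSS TAATTA had −0.77, CAYATG 0.16, TRTTTAC −0.21 and TATKATA −0.61. The cause was not tested for any of these. Of the values for single sites at summits not counted as turned, 137 stayed on their side of the threshold, 20 passed it newly and 19 no longer did. For single gene lists these counts were 200, 1 and 9. Values that passed in neither setting were counted as staying whatever their direction. TTAATKA, for example, had 0.35 among peaks above the median signal, against −0.01 in the main list. Of 75 named genes with a summit, 68 to 75 kept one under 5 settings, and of 36 without, 0 to 6 gained one. Depth is unknown, so how many weaker peaks a deeper library would add cannot be told. No paired analysis was possible because the series has 1 group.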

Other observations

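All tests in this part were chosen only after the data were seen, and none was fixed beforehand.

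Further families of general cellular function had more summits than matched genes, and several specialised families had fewer. Genes for mitochondrial ribosomal proteins had a summit within 2 kb at 59 of 73, against 26.5 for random genes matched on window length, complex I subunits of the respiratory chain at 30 of 40 against 16.8, and subunits of RNA polymerase II and Mediator at 31 of 38 against 16.9 (adjusted p = 0.000333 for each, n = 73, n = 40 and n = 38 genes, from the smallest raw p that 10000 random lists can give, over 10 families). Nuclear pore genes had one at 19 of 21 against 12.2 (adjusted p = 0.0035, n = 21 genes) and TBP-associated factors at 12 of 15 against 6.98 (adjusted p = 0.0136). Translation initiation factors had one at 29 of 44 against 23.1, which did not pass (adjusted p = 0.101, n = 44 genes). Cytochrome P450 genes, which encode enzymes of detoxification and hormone metabolism, had one at 18 of 85 against 46.3, ionotropic receptors at 12 of 60 against 32.2, and the Osiris genes at 0 of 25 against 12.7 (adjusted p = 0.000333 for each, n = 85, n = 60 and n = 25 genes). Odorant-binding proteins had one at 8 of 51 against 17.9 (adjusted p = 0.00314, n = 51 genes). As for the lists fixed beforehand, family members that lie side by side were counted as independent, so these p-values can be too small.

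Promoters shared by a pair of genes often held summits. Of 4648 genes whose TSS lies within 1000 bp of that of a gene transcribed the other way, 61.0% had a promoter summit, against 23.9% of the 9320 others, a ratio of 2.56. A single summit can count for both genes of a pair, so the shares are not of independent promoters, and no p is given. Of promoter summits, 1760 (38.4%) lay within 500 bp of the TSS of at least 2 genes. CGATA, the core of the site of BEAF-32, an insulator protein found between such gene pairs, was in 42.8% of summit windows and 11.9% of flank windows. It was in 76.6% of the 1144 strongest peaks and 15.6% of the 1144 weakest, and 54.7% of the strongest held at least 2 copies. Among the 15 strongest peaks 14 had CGATA and 1 had TATCGATA. No profile of BEAF-32 or DREF was used here.

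Below the listed score, the 71497 entries of the main ranked list were examined for weaker sites of Scr. In the 14299 strongest of these TTAATKA was in 3.32% of summit windows and 6.37% of flank windows, and TAATTA in 3.37% and 6.39%, but the scrambled TTATAA was lower by as much (2.87% and 5.43%). TTAATKA was not higher at summits than in flanks in any of the 5 equal parts of these entries by signal. In each of these parts TTAATKA and the Exd-Hox site TGATTDAT were lower by less than their scrambled forms TATKATA and TATGTDTA. Their log2 ratios were −0.58 against −0.93 and −0.47 against −0.87 in the second part, but −0.200 against −0.203 for TTAATKA in the weakest. TAATTA was lower by less than TTATAA except in the strongest and the weakest part. Sites were not tested against their scrambled forms. The share at promoters was 29.1% in the strongest part and 11.0% in the weakest.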
